A study of Mus musculus with 27 samples.

How the data were processed

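RNA was measured in 27 libraries of mouse thyroid tissue that was cut out by laser capture microdissection, in which chosen areas of a tissue section are dissected under a microscope. RNA was extracted with a kit for small amounts, and libraries were made with a QuantSeq kit, which sequences the 3′ end of polyadenylated transcripts, per the labels' protocols. The table holds raw read counts per gene that the authors deposited, with no normalization, since the values are whole numbers whose totals differ between libraries. STAR, featureCounts, DESeq2 and the mouse build GRCm38 are named without versions or roles, per the submitters' processing notes. The annotation release, the strand setting and any handling of molecular identifiers are not given in the sources used here. Whether reads of overlapping genes on opposite strands were told apart is therefore not known. Reads of near-identical copies, such as mitochondrial genes and their nuclear copies or the Gstm, Cyp2a and Slc22a families, could have been split or dropped, and values of such genes are uncertain.

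The groups came from the labels. NCT was normal thyroid of non-exposed mice, NT was normal-looking thyroid of exposed mice with lesions nearby, and PL was proliferative lesions of those exposed mice. Each group had 9 libraries from 9 mice, 6 female and 3 male. NT and PL libraries were paired by the mouse number in the labels. Within the 9 pairs the deviations from the group means correlated at -0.00646 to 0.233, on average 0.134, and 6 pairs were above 0.1. The average of -0.0165 for unmatched numbers follows largely from centring on the group means. The own partner correlated best for 4 of the 9 NT libraries and 3 of the 9 PL libraries. The pairing rests on the mouse numbers. The sex label matched the sex-linked transcripts in 27 of 27 libraries. None of the 108 pairs of libraries within groups matched within sampling noise, with a lowest chi-square per degree of freedom of 13.2.

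The table had 54532 gene rows, of which 54409 were matched to names by identifier in the GENCODE M21 annotation of GRCm38. The 123 rows that did not match held 0.0251% of counts. Coordinates are those of that annotation, counted from 1. Libraries held 2923851 to 14148601 counts. Levels are counts scaled to a common library size (CPM) with factors from the trimmed mean of M values (TMM) over all 27 libraries, given as mean ± SD.

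Each comparison was fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default filterByExpr filter (minimum count 10), robust dispersion and Benjamini-Hochberg adjustment at 0.05. Only the libraries of the 2 groups compared entered each fit. The PL against NT fit kept the mouse as a block. The other comparisons set different animals against each other and had no covariate. Standard errors (SE) of log2 fold changes were taken as the size of the fold change divided by the square root of F, which is approximate. Whether changes differed between the sexes was tested as an interaction.

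Before the data were examined, 27 gene lists were fixed from textbook knowledge for thyroid differentiation, markers of human papillary thyroid carcinoma, signalling, stress, metabolism and the cell types that captured tissue could hold. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Genes to be named were also fixed by rule. The rule took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 10 CPM and the same direction in at least 7 of 9 pairs or libraries, up to 4 members of each list by smallest p, the best member of a list with no call, and a fixed set of genes that included Tg, Slc5a5, Pax8, Nkx2-1, Tshr, Lgals3, Cdkn1a and Mki67. Some genes that the rule picked are not reported. Predicted genes and pseudogenes were counted and not named under the rule. Pth, Lipf, Lyz2, Ucp1, Cidea, Adipoq, B330016D10Rik and a lysosome list with its members were singled out after their values were seen.

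Alternatives covered DESeq2 size factors, upper-quartile factors, the Wald test of DESeq2 1.42.0, limma-voom with quality weights on all libraries, no filter, a stricter filter of 10 counts in 9 libraries, removal of the 10 most abundant genes, a 2-fold cutoff, females only, each library or pair left out, the fit without the block, and sex or the mouse number series as a covariate. For the comparisons with NCT, a fit of all 27 libraries was planned too. After the data were seen, fits without libraries over 2000 CPM of Pth or Lipf, with an adipocyte marker score as a covariate, and within the number series shared best by the groups were added. Splits of the libraries into groups of the same sizes were drawn with a fixed seed, 40 for PL against NT and for each sex test and 60 for each other comparison, the actual grouping counted among them.

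The procedure was tested on simulated counts with known changes. For PL against NT, 24.2% of 1.5-fold, 53.8% of 2-fold and 85.2% of 4-fold changes were recovered, with 0 of 13803 unchanged genes called. For NT against NCT the shares were 20.9%, 47.0% and 90.8%, with 4 of 14005 called. For PL against NCT they were 16.7%, 59.4% and 96.8%, with 5 of 13727 called. Most 1.5-fold changes thus went undetected in the simulation. Each gene was drawn independently, so structure shared by genes of a library beyond the fitted means, such as captured tissue, was absent. The low numbers of false calls thus need not hold for the real libraries. The share recovered also depends on how many genes change.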

Results

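The series asked how gene expression in proliferative lesions of the mouse thyroid after radiation differs from normal thyroid. Laser-captured tissue gave 27 libraries of 3′ end RNA counts in 3 groups of 9, namely normal thyroid of non-exposed mice (NCT), normal tissue of exposed mice next to lesions (NT) and the lesions themselves (PL), paired with NT by mouse. Dose, strain and age of the animals are not in the labels. Median totals were 4622595 counts in NCT, 7220957 in NT and 6479022 in PL, and 17180 to 21213 genes had a count in a library. Tg, the gene of the thyroid hormone precursor thyroglobulin, took 3.00% of all counts. Mitochondrially encoded transcripts took 14.0% ± 3.63 (SD, n = 9) of counts in NCT, 10.8% ± 1.94 in NT and 10.4% ± 1.59 in PL.

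Some libraries held high levels of transcripts known from other tissues. Pth, the parathyroid hormone gene, was above 2000 CPM in PL replicate 2 (27677), NT replicates 9 (25924) and 7 (18232) and NCT replicates 5 (4488) and 8 (2427). NCT replicate 9 held Lipf, a gastric lipase gene known from glandular epithelium, at 9970 CPM, against 7.64 to 29.0 CPM in the other libraries, and Lyz2, a lysozyme gene, at 16823 CPM. Ucp1, the uncoupling protein of brown fat, averaged 212 ± 203 CPM in NCT, 29.2 ± 34.4 in NT and 32.3 ± 47.9 in PL (SD, n = 9 each).

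**Figure D1:**
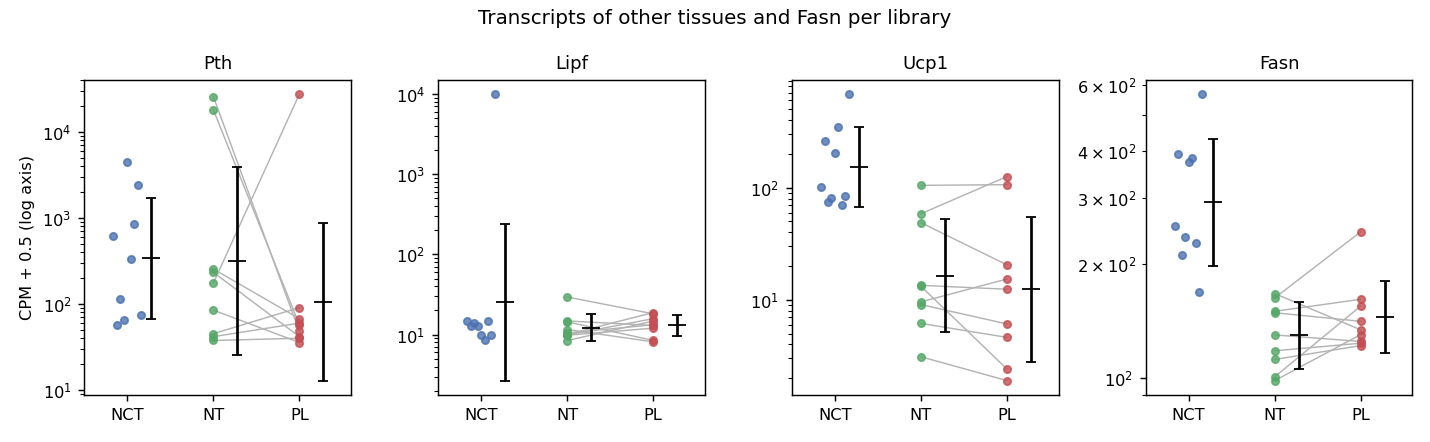
Level per library (CPM + 0.5, log axis) of Pth, Lipf, Ucp1 and Fasn in NCT, NT and PL. Points are libraries, grey lines join NT and PL of a mouse, and black marks are the mean ± SD on the log scale (n = 9 per group). Pth is above 2000 CPM in 5 libraries and Lipf in 1, and Fasn is higher in NCT (313 ± 126 CPM) than in NT (131 ± 26.4 CPM).

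Lesions were compared with normal tissue of the same mouse to find what marks the lesion itself. Transcripts of C cells, the calcitonin-producing cells of the thyroid, were far lower in lesions. Calca, which encodes calcitonin, fell from 1885 ± 1604 CPM in NT to 85.7 ± 99.3 CPM in PL (log2 fold change -4.49, SE 0.61, adjusted p = 0.00989), lower in 9 of 9 mice. In the same mice Tshr, the receptor of thyrotropin, rose from 84.8 ± 46.4 to 204 ± 76.1 CPM (SD, n = 9). Slc5a8, an anion transporter of the apical follicular membrane, fell from 41.6 ± 16.4 to 15.5 ± 8.0 CPM. Sod3, an extracellular superoxide dismutase, rose from 114 ± 67.2 to 331 ± 157 CPM. In all, 445 of 14461 tested genes passed the threshold, 255 higher and 190 lower in PL, and 201 of them changed at least 2-fold.

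The largest rises were those of Cck, which encodes the peptide hormone cholecystokinin (log2 fold change 3.84, SE 0.44, adjusted p = 0.00537), Elobl (3.78, SE 0.66, adjusted p = 0.0211), Col25a1, a membrane collagen (3.25, SE 0.59), Hs3st4, a heparan sulfate sulfotransferase (3.22, SE 0.47), and Slc22a19, an organic anion transporter (3.21, SE 0.58). Muc4, a membrane mucin, rose by 2.69 (SE 0.60), Slc34a2, a sodium-phosphate cotransporter, by 2.50 (SE 0.52) and Atp2b2, a plasma membrane calcium pump, by 2.48 (SE 0.50) on the log2 scale. Slc34a2 was higher in 8 of 9 mice and the others in 9 of 9. Cck went from 6.37 ± 8.08 to 99.6 ± 111 CPM and Slc34a2 from 22.3 ± 11.6 to 148 ± 117 CPM, so lesions differed widely among themselves.

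**Figure D2:**
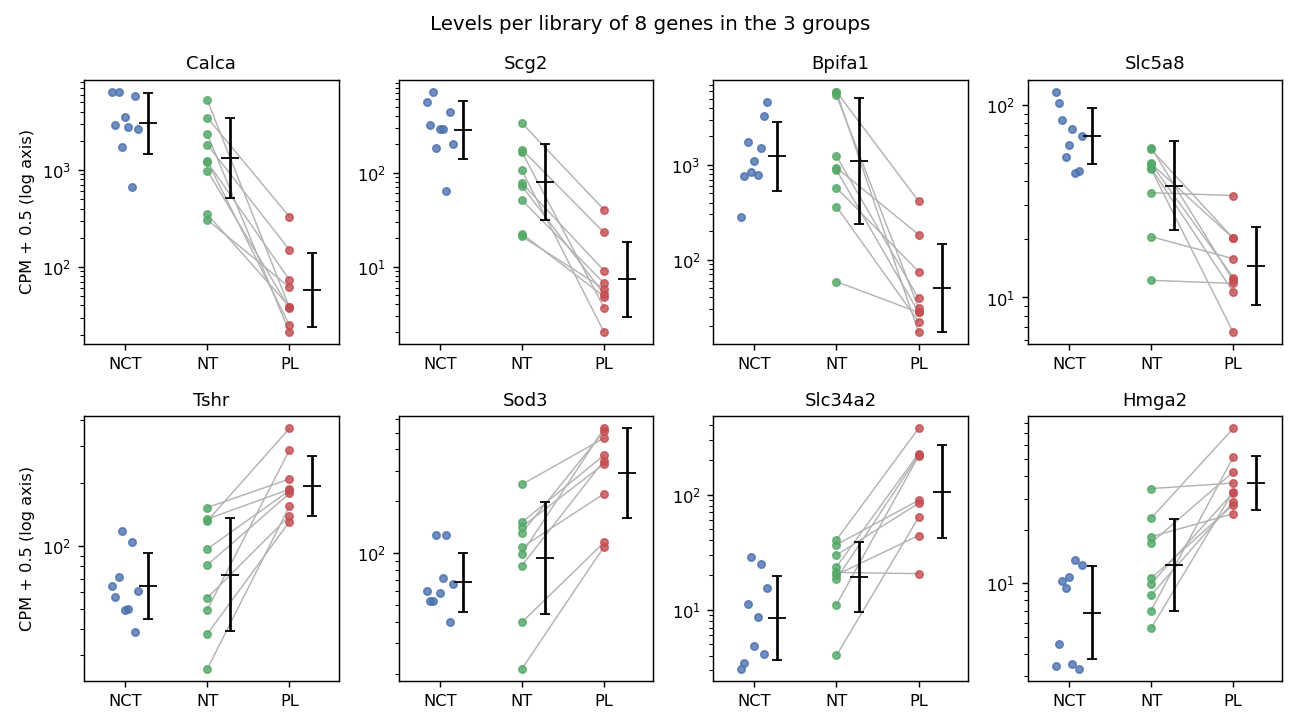
Level per library (CPM + 0.5, log axis) of 8 genes in NCT, NT and PL. Points are libraries, grey lines join NT and PL of a mouse, and black marks are the mean ± SD on the log scale (n = 9 per group). Calca, Scg2, Bpifa1 and Slc5a8 are lower in PL than in NT in 9 of 9 mice, and Tshr, Sod3 and Hmga2 are higher in 9 of 9.

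Of the 10 C cell markers, 5 fell and 1 rose over all genes, and the counts were the same adjusted over the list alone. The fallen members included Calca, Scg2 and Chgb, which encode hormone and granule proteins (Scg2 -3.52, SE 0.45; Chgb -3.37, SE 0.52), and Pcsk2, a prohormone convertase (-4.31, SE 0.65). Scg5, a chaperone of that convertase which many secretory cells make, rose by 1.43 (SE 0.23, adjusted p = 0.0104). The list passed camera at adjusted p = 0.00048, and adjusted p = 0.239 with an estimated correlation. Markers of airway and squamous epithelium were also lower, with 3 of 8 tested members fallen over all genes and 5 adjusted over the list alone (adjusted p = 1.716e-05, and adjusted p = 0.239 with an estimated correlation). Bpifa1, a secreted airway protein, fell from 2356 ± 2549 to 92.8 ± 132 CPM, Reg3g, an antimicrobial lectin, by -3.34 (SE 0.62) and Tppp3, a gene of ciliated cells, by -1.60 (SE 0.37). Fry called these lists as well (adjusted p = 0.00365 for C cells and 0.00541 for airway) and no other. Further large falls were those of Scgb3a2, a secretoglobin of the airway (-4.57, SE 0.88), Sec14l3 (-4.31, SE 0.88), Spink5, a protease inhibitor of stratified epithelium (-4.15, SE 0.88), and Cyp2a5, a cytochrome P450 with near-identical copies (-4.06, SE 0.83). Bpifa1 was at 5402 to 5896 CPM in NT replicates 7 to 9 and at 58.2 to 1234 CPM in the other NT libraries. Its fall was seen in 9 of 9 mice, and whether airway or squamous tissue was captured with the normal tissue was not tested.

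Thyroid differentiation genes moved in both directions. Of 22 tested members, Tshr (1.40, SE 0.23, adjusted p = 0.0117) and the transcription factor Glis3 (0.84, SE 0.21, adjusted p = 0.0413) rose, and Slc5a8 (-1.43, SE 0.31, adjusted p = 0.0325) and Duoxa1, a maturation factor of the dual oxidases (-1.54, SE 0.39, adjusted p = 0.0491), fell. Adjusted over the list alone, 5 rose and 3 fell, and the list passed no test of a common direction (camera adjusted p = 0.241). Tg (-0.24, SE 0.19, adjusted p = 0.567), Slc5a5, the iodide importer (0.16, SE 0.71, adjusted p = 0.938), and the thyroid transcription factors Pax8 (0.57, SE 0.20, adjusted p = 0.145) and Nkx2-1 (0.62, SE 0.20, adjusted p = 0.119) did not pass. Tg was at -0.10 without replicate 7 and Slc5a5 at -0.22 without replicate 9. Tshr lies on chromosome 12 (91384563 to 91549808, plus strand) and Slc5a8 on chromosome 10 (88885992 to 88929515, plus strand) of GRCm38.

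Of 18 tested markers of human papillary thyroid carcinoma, 3 rose and 1 fell over all genes, and 3 rose and 4 fell adjusted over the list alone. Hmga2, a chromatin architecture protein, rose from 14.4 ± 9.28 to 38.5 ± 15.6 CPM (1.56, SE 0.27), and Slc34a2 and Dpp4, a cell surface peptidase (1.16, SE 0.28), rose as well. S100a6, a calcium-binding protein, fell by -1.41 (SE 0.29), and Lgals3, the galectin used as a carcinoma marker, was at -0.96 (SE 0.41, adjusted p = 0.260). The list passed no test of a common direction (camera adjusted p = 0.738). Antioxidant genes split likewise, with 3 of 21 higher and 2 lower over all genes and adjusted over the list alone (camera adjusted p = 0.546). Sod3 (1.63, SE 0.17, adjusted p = 0.00142) and the peroxiredoxins Prdx4 (0.98, SE 0.16) and Prdx1 (0.48, SE 0.11) rose, and the glutathione transferase Gstm1 fell by -1.20 (SE 0.23).

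Among 21 secretory chaperones Pdia6 and Pdia3, disulfide isomerases of the endoplasmic reticulum, and Manf, a stress-induced secreted protein, rose by 0.60 (SE 0.14), 0.57 (SE 0.15) and 0.62 (SE 0.15). Adjusted over the list alone 9 rose and 1 fell, and the list passed at adjusted p = 0.00136 (adjusted p = 0.599 with an estimated correlation). No cell cycle gene of 27 passed over all genes and 4 rose adjusted over the list alone, with a list median of 0.37 (adjusted p = 0.00066, and adjusted p = 0.599 with an estimated correlation). Mki67, a marker of dividing cells, was at 0.42 (SE 0.23, adjusted p = 0.363). Of 24 p53 targets Cdkn1a, a cell cycle inhibitor, fell from 188 ± 35.3 to 131 ± 30.3 CPM (-0.54, SE 0.13, adjusted p = 0.0333) and Perp, a desmosomal protein, fell by -0.63 (SE 0.15). That list had 6 lower adjusted over the list alone and passed at adjusted p = 0.0237 (adjusted p = 0.599 with an estimated correlation). Phlda1 of the MAPK output genes (0.58, SE 0.12) and the clock gene Per2 (0.95, SE 0.23) were the 1 call of their lists, over all genes and adjusted over the list alone (camera adjusted p = 0.595 and 0.282). Of the glycolysis and hypoxia list none passed over all genes, with Ndrg1 at 1.07 (SE 0.29, adjusted p = 0.0711), and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.546).

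Stromal and blood cell markers were lower as lists. Fibroblast and matrix genes had a median of -0.39, with 1 of 20 fallen over all genes (Col6a2, a collagen VI chain, -1.24, SE 0.21) and 8 adjusted over the list alone (adjusted p = 0.00048, and adjusted p = 0.599 with an estimated correlation). Endothelial markers (median -0.37, adjusted p = 0.00048), interferon response genes (-0.37, adjusted p = 0.0115), macrophage markers (-0.33, adjusted p = 0.0162), T and NK cell markers (-0.66, adjusted p = 0.0237), pericyte and smooth muscle markers (-0.34, adjusted p = 0.0315), red blood cell markers (-0.61, adjusted p = 0.0381) and adipocyte markers (-0.58, adjusted p = 0.0410) passed too. With an estimated correlation these 8 lists had adjusted p from 0.599 to 0.735. Over all genes they held 3 calls, Col6a2, the macrophage scavenger receptor Cd163 (-1.84, SE 0.44) and Myl9, a myosin light chain of smooth muscle (-1.27, SE 0.25). Adjusted over the list alone the falls numbered 2 each for endothelial, interferon and pericyte lists, 1 for macrophages and 0 for the T and NK, red blood cell and adipocyte lists. The nuclear oxidative phosphorylation, mitochondrially encoded, immediate early, antigen presentation, B and plasma cell, parathyroid, skeletal muscle and cartilage lists passed neither as lists nor in any member.

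The number of calls depended on the mice. Without the 3 mice that had a library over 2000 CPM of Pth, 95 genes passed (79 higher, 16 lower), 80 of them among the 445. Of 40 called genes that the naming rule picked, 7 kept their call (Cck, Chgb, Scg2, Sod3, Prdx4, Dpp4 and Cyp2a5) with no change of direction. In the 6 females alone 6 genes passed, all of them higher, and 38 of 40 such calls ended. Those of Cck (3.74) and Sod3 (1.53) stood, while Calca was at -3.80 (adjusted p = 0.0563) and Tshr at 1.23 (adjusted p = 0.141). Leaving out 1 mouse gave 257 genes without replicate 2, 209 without replicate 3, 240 without replicate 4, 234 without replicate 7 and 137 without replicate 8. In each of the 9 fits that left out 1 mouse the calls of Calca, Cck, Chgb, Col6a2, Gstm1, Hmga2, Hs3st4, Pcsk2, Prdx4, Scg2, Scg5, Slc22a19, Sod3 and Tshr stood. The calls of Myl9 and Phlda1 stood in 8 fits, Col25a1 and Elobl in 7, Atp2b2 in 6, S100a6 in 5, Cdkn1a, Cyp2a5 and Slc5a8 in 4. They stood for Bpifa1, Dpp4, Muc4, Pdia6, Perp, Prdx1, Scgb3a2 and Sec14l3 in 3, Cd163, Duoxa1, Manf, Per2, Slc34a2 and Tppp3 in 2 and Glis3 and Pdia3 in 1, and those of Reg3g and Spink5, tested in 7 fits, in 6 and 2. The fold changes of these called genes moved by at most 1.25 times in these fits, so the lost calls came with small moves. Without the mouse block the calls of Sod3 (adjusted p = 0.0528), Per2 (0.222), Prdx1 (0.174), Duoxa1 (0.461), Atp2b2 (0.0619), Cd163 (0.115), Manf (0.0555) and Perp (0.0769) ended and Ndrg1 passed (0.0205). The adipocyte (0.0874) and red blood cell (0.0598) lists did not pass. Without the same 3 mice 7 lists passed, and those of p53 targets (0.159), chaperones (0.0520), fibroblasts (0.0853), pericytes (0.188), adipocytes (0.785) and red blood cells (0.238) did not.

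**Figure D3:**
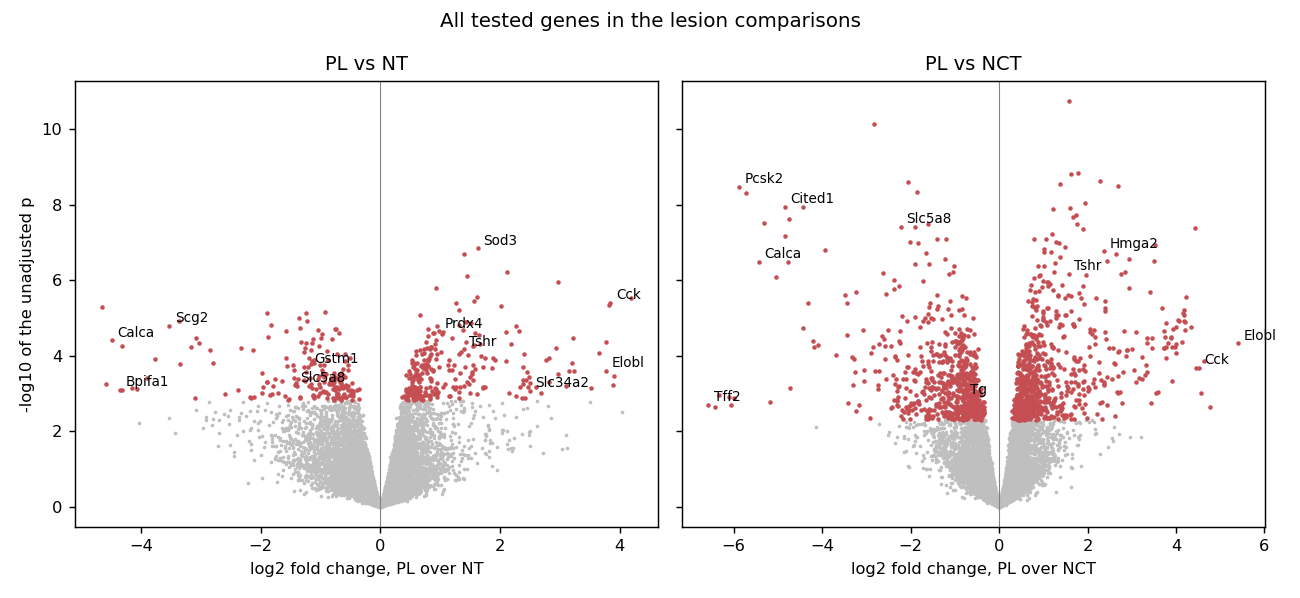
Each tested gene by log2 fold change (x) and -log10 of its unadjusted p (y) for PL over NT and PL over NCT. Red points passed an adjusted p of 0.05, 445 of 14461 genes for PL over NT and 1433 of 14234 for PL over NCT.

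Normal tissue of exposed mice was compared with that of non-exposed mice. Every exposed mouse here bore a lesion. Effects of exposure, of bearing a lesion and of lying next to one thus cannot be told apart in this comparison. Fasn, the fatty acid synthase, fell from 313 ± 126 CPM in NCT to 131 ± 26.4 in NT (log2 fold change -1.25, SE 0.20, adjusted p = 0.0164), and Agpat2, an acyltransferase of glycerolipid synthesis, from 60.9 ± 31.5 to 22.8 ± 7.38 CPM (-1.40, SE 0.23, adjusted p = 0.0164). Runx1, a transcription factor of blood and epithelial cells, rose from 16.9 ± 5.27 to 34.1 ± 7.40 CPM (1.02, SE 0.19, adjusted p = 0.0390). In each case 9 of 9 NT libraries lay on that side of the NCT median. The fourth of the 4 calls among 14447 genes was the pseudogene B330016D10Rik (-2.20, SE 0.37, adjusted p = 0.0164), outside the naming rule and named after its values were seen. At an unadjusted p under 0.05 there were 1673 genes. Fasn lies on chromosome 11 (120805846 to 120824547, minus strand) and Runx1 on chromosome 16 (92601466 to 92826149, minus strand) of GRCm38.

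Adipocyte markers were lower as a list in NT, with a median of -1.36, 0 of 10 passing over all genes and 9 fallen adjusted over the list alone (camera adjusted p = 6.765e-12, adjusted p = 0.270 with an estimated correlation, fry adjusted p = 0.0371). Lpl, lipoprotein lipase, went from 429 ± 252 to 213 ± 41.5 CPM (-1.01, SE 0.26, adjusted p = 0.149), and the brown fat transcripts Ucp1 and Cidea (115 ± 142 CPM in NCT, 17.2 ± 13.6 in NT) moved with the group. Genes of the respiratory chain were lower as lists beside them. Nuclear oxidative phosphorylation genes had a median of -0.34, with 7 of 31 fallen adjusted over the list alone (adjusted p = 6.765e-12), and mitochondrially encoded genes one of -0.53, with 11 of 13 fallen adjusted over the list alone (adjusted p = 1.002e-10). Both had adjusted p = 0.388 with an estimated correlation. No member of either passed over all genes, with Atp5a1, a subunit of the ATP synthase, at -0.41 (SE 0.12, adjusted p = 0.207) and mt-Nd6 at -1.52 (SE 0.34, adjusted p = 0.0905). Reads of mitochondrial genes are partly shared with nuclear copies, so their values are uncertain. With an adipocyte marker score as a covariate, chosen after seeing the data, no gene passed, Fasn was at -0.53 (SE 0.20), and the medians were -0.21 for mitochondrially encoded and -0.14 for nuclear respiratory genes.

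Lists of immune and dividing cells were higher in NT, without a member past the threshold over all genes. They were macrophage markers (median 0.48, adjusted p = 0.00034), cell cycle genes (0.30, adjusted p = 0.00099), antigen presentation (0.39, adjusted p = 0.00121) and interferon response genes (0.36, adjusted p = 0.00249), each at adjusted p = 0.506 with an estimated correlation. Examples were Fcer1g, an immune receptor chain (0.78, SE 0.25, adjusted p = 0.254), Tpx2, a spindle protein (0.85, SE 0.38, adjusted p = 0.393), Tapbp, a peptide loading factor (0.48, SE 0.15, adjusted p = 0.208), and Irf7, an interferon regulatory factor (1.34, SE 0.49, adjusted p = 0.301). Without NT replicate 6 Fcer1g was at 0.51 and Irf7 at 0.80. Markers of papillary carcinoma passed as a list (0.34, adjusted p = 0.00812, and adjusted p = 0.388 with an estimated correlation), with Ccnd1, cyclin D1, at 0.64 (SE 0.16, adjusted p = 0.121) and Lgals3 at 1.02 (SE 0.27, adjusted p = 0.161). Adjusted over the list alone 2 of these rose and 1 fell, 1 antigen presentation gene rose, and no macrophage, cell cycle or interferon gene passed. C cell markers were lower (median -0.96, 2 fallen adjusted over the list alone, adjusted p = 0.00112, and adjusted p = 0.388 with an estimated correlation), as were the chaperones (-0.21, adjusted p = 0.0172, and adjusted p = 0.506 with an estimated correlation). Thyroid differentiation genes had a median of -0.00 with a test direction of lower (4 fallen adjusted over the list alone, adjusted p = 0.0152), and skeletal muscle markers a test direction of lower against a median of 0.89 (adjusted p = 0.00099), both at adjusted p = 0.506 with an estimated correlation. Tg was at -0.55 (SE 0.18, adjusted p = 0.254) and Pax8 at -0.39 (SE 0.10, adjusted p = 0.141). None of the lists of MAPK output, p53 targets, glycolysis and hypoxia, antioxidants, immediate early, clock, T and NK cells, B and plasma cells, fibroblasts, endothelium, pericytes, parathyroid, airway or red blood cells passed, with adjusted p from 0.0594 to 0.895, and cartilage had too few members to test. Adjusted over the list alone they held 1 rise, in the clock list, and 1 fall, in the airway list. The test direction was lower against a median above 0 for B and plasma cells (0.42), airway (0.30) and pericytes (0.03), and higher against -0.01 for immediate early genes.

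Calls ended in some fits with fewer libraries. No gene passed without NT replicate 4, without NT replicate 6 or without the 4 libraries over 2000 CPM of Pth, 1 passed without NT replicate 2, 12 without NCT replicate 7 and 9 without NCT replicate 8. Fasn passed in 16, Agpat2 in 15 and Runx1 in 6 of the 18 fits that left out 1 library. Their fold changes stayed near those with all libraries in these fits, from -1.33 to -1.10 for Fasn, -1.54 to -1.16 for Agpat2 and 0.93 to 1.10 for Runx1. So they did without the libraries high in Pth (-1.22, -1.40 and 1.09, and -2.22 for B330016D10Rik, adjusted p = 0.0762 each). With upper-quartile factors Runx1 was at 1.02 (adjusted p = 0.0550) and no rise passed. Mouse numbers began with series that were uneven between groups, with 4, 1 and 4 NCT mice and 1, 4 and 4 NT mice in the 3 series, whose meaning the labels do not give. With the series as a covariate 7 genes passed, 3 of them among the 4, and Fasn was at -1.44 (SE 0.21). Within the series that both groups share best, a fit of 4 against 4 mice chosen after seeing the data, no gene passed, with Fasn at -1.46, Agpat2 at -1.64 and Runx1 at 0.83 (adjusted p = 0.986 each). Its controls include NCT replicates 6 and 9, the controls highest in Ucp1, of which replicate 9 is also the library high in Lipf. These had 384 and 567 CPM of Fasn, against 227 and 168 CPM in NCT replicates 7 and 8. NCT replicate 8 and NT replicates 7 and 9 of this series are high in Pth. The list calls of thyroid differentiation (0.550) and skeletal muscle (0.211) ended without the libraries high in Pth, and T and NK cells passed (0.00897). Without NCT replicate 9 that of the chaperones ended (0.0638) and red blood cells passed (0.0265).

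**Figure D4:**
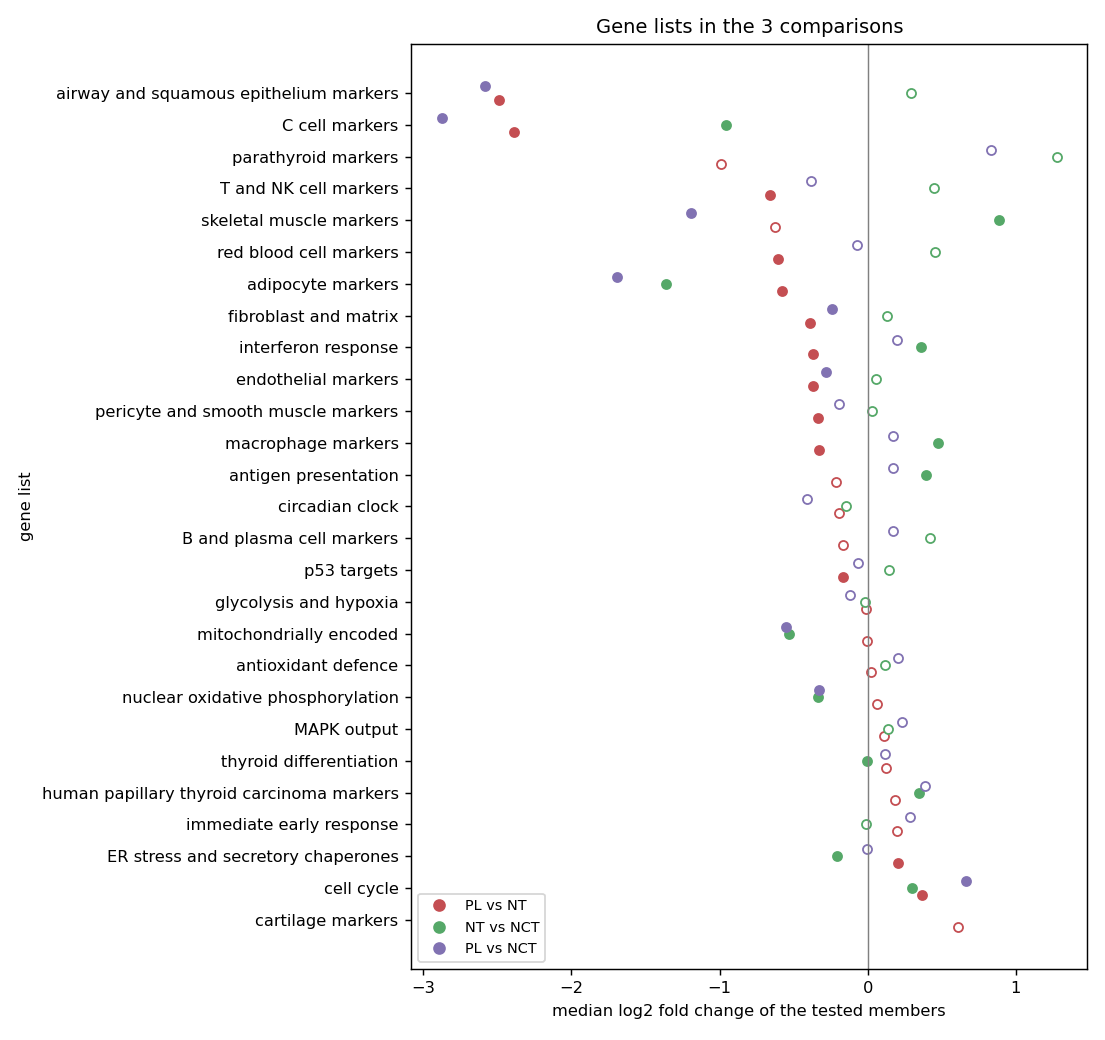
Median log2 fold change (x) of the tested members of each gene list (y) in the 3 comparisons. Filled points passed camera with the preset correlation at an adjusted p of 0.05, 13 lists for PL vs NT, 12 for NT vs NCT and 9 for PL vs NCT, and open points did not. With an estimated correlation 0 lists passed.

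Lesions were last compared with thyroid of non-exposed mice, from other animals. Here 1433 of 14234 genes passed, 776 higher and 657 lower, 625 of them by at least 2-fold. C cell transcripts were far lower, with Pcsk2 from 94.9 ± 50.4 CPM in NCT to 1.73 ± 1.48 in PL (log2 fold change -5.88, SE 0.54, adjusted p = 5.23e-06) and Calca from 3660 ± 2096 to 85.7 ± 99.3 CPM (-5.43, SE 0.67). Tshr rose from 67.9 ± 26.5 to 204 ± 76.1 CPM (1.57, SE 0.23), and Tg fell from 39648 ± 11060 to 23421 ± 8079 CPM (-0.77, SE 0.21, adjusted p = 0.0210). This comparison shares its libraries with the others and is not independent of them.

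The largest rises were Elobl (5.41, SE 0.99), Coch, an extracellular matrix protein (4.77, SE 1.33), Lcn2, an iron-binding lipocalin (4.55, SE 1.14), Cck (4.53, SE 0.95), Col25a1 (4.23, SE 0.63), Hs3st4 (4.20, SE 0.72), Gcnt3, a mucin glycosyltransferase (4.14, SE 0.77), and Muc4 (4.01, SE 0.69). Coch lost its call without PL replicate 8 (2.71, adjusted p = 0.103). That library had 319 CPM against at most 23.8 in the other lesions. The largest falls other than those of Pcsk2 and Calca came from NCT replicate 9, the library high in Lipf. Tff2, a trefoil peptide, was at -6.57 with all libraries and -0.11 (adjusted p = 0.892) without it, and Wfdc18 at -6.05 and -0.52 (adjusted p = 0.530). Scgb3a1 was at -6.09 and -1.46 (adjusted p = 0.0509), Dmbt1, a mucosal scavenger protein, at -6.00 and -1.20 (adjusted p = 0.0645), Ltf, lactotransferrin, at -5.18 and -1.52 (adjusted p = 0.123), and A2ml1, a protease inhibitor, at -6.33 and -1.16 (adjusted p = 0.0179). Without that library 1219 genes passed, and without the 3 libraries over 2000 CPM of Pth 1136. Of the genes the naming rule picked, 19 of 72 calls ended without NCT replicate 9, among them Coch (adjusted p = 0.0517), Dcn (0.0713) and Lum (0.0619). Without the libraries high in Pth 14 of 71 ended, among them Coch (0.0919), Ltf (0.0516), Dcn (0.0998) and Lum (0.131), and 10 lists passed, with antigen presentation added (0.0473). The mouse number series were as uneven here, and with the series as a covariate 1126 genes passed, 983 of them among the 1433. It ended 20 of 72 calls of the naming rule, among them Coch (adjusted p = 0.0771), Per2 (0.169) and Bnip3 (0.144), while Calca was at -5.78 and Tshr at 1.71. In females 450 genes passed and 44 of 71 such calls ended, among them Tg (-0.90, adjusted p = 0.0795) and Cck (4.14, adjusted p = 0.0610). Within the mouse number series that both groups share best, 4 against 4 mice, 264 genes passed, 216 of them among the 1433, with Calca at -5.63 (adjusted p = 0.0364) and Tshr at 1.71 (0.0511), and the call of Tg ended (0.117).

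Of 23 thyroid differentiation genes 5 rose and 4 fell, over all genes and adjusted over the list alone. Besides Tshr, which rose, Slc5a8 (-2.22, SE 0.27, adjusted p = 2.303e-05) and Thra, a thyroid hormone receptor (-0.73, SE 0.14, adjusted p = 0.00147), fell, while Slc5a5 (0.43, SE 0.41, adjusted p = 0.581) and Pax8 (0.27, SE 0.19, adjusted p = 0.443) did not pass. PL replicate 9 held 506 CPM of Slc5a5 against at most 188 in the other lesions, and without it Slc5a5 was at -0.13 and Pax8 at 0.14. Of 19 papillary carcinoma markers 8 rose and 3 fell (8 and 4 adjusted over the list alone), without a common direction (camera adjusted p = 0.244). Slc34a2 (3.73, SE 0.64), Hmga2 (2.37, SE 0.32) and the integrin chain Itga3 (1.33, SE 0.22) rose, and the transcriptional coactivator Cited1 fell from 7.52 ± 2.84 to 0.262 ± 0.287 CPM (-4.85, SE 0.57, adjusted p = 1.132e-05), opposite to its use as a marker of the human tumour. NT libraries, not part of this fit, held 0.287 to 5.01 CPM of Cited1. Each was thus below the NCT mean, so part of the fall was already present beside lesions. The lesion values lay near the floor. Cell cycle genes rose, 7 of 25 over all genes and 11 adjusted over the list alone, among them Cenpe, a kinetochore motor (1.23, SE 0.25), Mcm2 of the replicative helicase (adjusted p = 0.00373), Ube2c (1.52, SE 0.38) and Tpx2 (1.55, SE 0.40). Mki67 rose from 10.9 ± 4.47 to 23.0 ± 10.1 CPM (1.07, SE 0.30, adjusted p = 0.0253), and this call ended in 2 of the 18 fits that left out 1 library. The list passed at adjusted p = 2.634e-06 (fry 0.0232, and adjusted p = 0.411 with an estimated correlation).

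C cell markers had 5 fallen and 2 risen members of 10 over all genes and adjusted over the list alone (adjusted p = 1.465e-05, and adjusted p = 0.115 with an estimated correlation). Airway markers had 5 fallen of 7, and 6 adjusted over the list alone (adjusted p = 8.028e-06, and adjusted p = 0.115 with an estimated correlation), with Krt5, a basal keratin, at -2.58 (SE 0.52) and Bpifa1 at -4.18 (SE 0.78). Mitochondrially encoded genes fell, 6 of 13 over all genes and 8 adjusted over the list alone (median -0.55, adjusted p = 8.028e-06, and adjusted p = 0.585 with an estimated correlation), such as mt-Nd2 from 10118 ± 2946 to 5803 ± 1040 CPM. Nuclear oxidative phosphorylation genes had 3 fallen of 31 and 0 adjusted over the list alone (adjusted p = 0.000149, and adjusted p = 0.645 with an estimated correlation). NCT replicates 6 and 9, the libraries highest in Ucp1 (348 and 684 CPM), also had the largest mitochondrial shares of counts. The calls of mt-Nd2, mt-Cytb, mt-Nd4l and mt-Nd5 stood in each of the 18 fits that left out 1 library. In NT against NCT the adipocyte score moved the medians of these lists to -0.21 and -0.14. That score was not fitted here, so the part of captured fat in either fall was not tested. Adipocyte markers were lower as a list (median -1.69, 0 over all genes and 8 adjusted over the list alone, adjusted p = 1.728e-06, and adjusted p = 0.411 with an estimated correlation), beside the higher Ucp1 of NCT. Fibroblast and matrix genes had 4 fallen over all genes and 5 fallen and 1 risen adjusted over the list alone (adjusted p = 0.00281), among them Pdgfra, a growth factor receptor (-1.22, SE 0.25), and the proteoglycans Dcn (-1.25, SE 0.38) and Lum (-1.10, SE 0.33), whose calls stood in 4 of the 18 fits that left out 1 library. Endothelial (adjusted p = 0.0142) and skeletal muscle markers (adjusted p = 0.00135) were lower as well, and these 3 lists were at adjusted p = 0.645 with an estimated correlation. Fry called the C cell, airway, adipocyte, cell cycle and mitochondrially encoded lists.

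Further lists passed no test of a common direction and held single changes. Of the antioxidant genes 4 rose and 3 fell, among them Sod3 (2.18, SE 0.33), Prdx4 (1.19, SE 0.24) and Gstm1 (-1.23, SE 0.17), with 5 and 3 adjusted over the list alone. The chaperones had 5 risen and 1 fallen, with Calr, calreticulin, from 1268 ± 176 to 1977 ± 343 CPM (0.63, SE 0.12) and Pdia4 (0.66, SE 0.14). In the glycolysis and hypoxia list, 3 rose and 3 fell, as in Ndrg1 (1.24, SE 0.18), Pdk1, a kinase of pyruvate dehydrogenase (-0.89, SE 0.21), and Bnip3, a mitophagy receptor (-0.60, SE 0.17). MAPK output had 2 risen, p53 targets 3 fallen, the clock list 1 risen and 2 fallen, immediate early, antigen presentation and interferon lists 1 risen each and pericytes 1 fallen. Cdkn1a was at -0.22 (SE 0.14, adjusted p = 0.374) and Lgals3 at 0.10 (SE 0.31, adjusted p = 0.893), but at -0.07 without PL replicate 1 and -0.01 without PL replicate 5. Adjusted over the list alone the counts were 5 risen and 1 fallen for chaperones, 3 and 4 for glycolysis and hypoxia, 3 and 0 for MAPK output, 2 and 4 for p53 targets, 1 and 4 for the clock, 3 and 0 for antigen presentation, 1 and 0 for immediate early genes, 0 for interferon and 0 and 1 for pericytes. Camera adjusted p of these lists and of the thyroid list ran from 0.0702 to 0.791. No macrophage, T and NK, B and plasma, parathyroid or red blood cell marker passed. The test direction was lower against a median above 0 for parathyroid (0.83) and B and plasma cells (0.17), and higher against -0.00 for chaperones.

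No gene passed the edgeR test of a difference in fold change between the sexes. How large a difference it could have detected was not simulated. The interaction of sex with PL against NT called 0 of 14461 genes in edgeR (401 at an unadjusted p under 0.05), and that with NT against NCT 0 of 14447 (412), on 6 female and 3 male mice per group. DESeq2 called 2 genes in the first, Spink5 and the fat gene Cidea, named after their values were seen, and 0 in the second.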

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

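Of the tests in this part, the splits of the libraries were planned before the data were seen, but the number for PL against NT was lowered to 40 and 10 after a longer run had been seen. Set beforehand too was the mouse number series as a covariate, which was turned to the question below after its result was seen. The fits without the mice high in Pth and with the adipocyte score were added after the data but before their own results were seen. The other tests were chosen after the result was seen.

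Each value here is the gap of the highest or lowest library to its nearest neighbour divided by the range of its group of 9, on log2(CPM + 2), or on counts for totals. Of 276 groups tested 22 exceeded Dixon's critical value, where chance flags about 5 percent of groups, or 13.8. Of the 22, 8 came from NCT replicate 9, and the 14 others were about as many as chance gives. That library stood high for Tff2 (0.903, 2792 CPM), Wfdc18 (0.846, 1275 CPM), A2ml1 (0.793, 15134 CPM), Dmbt1 (0.710, 4030 CPM), Reg3g (0.683, 581 CPM), Scgb3a1 (0.640, 2616 CPM), Ltf (0.619, 6714 CPM) and Agpat2 (0.528, 140 CPM). NT replicate 9 was low for Slc5a5 (0.673, 3.21 CPM). NT replicate 6 was high for Irf7 (0.536, 89.1 CPM) and Mki67 (0.524, 50.5 CPM) and low for Pdk1 (0.530, 7.90 CPM). NCT replicate 7 was high for Elobl (0.645, 9.71 CPM) and low for Cited1 (0.599, 1.49 CPM). PL replicate 8 was high for Ctsa (0.509, 497 CPM) and Coch (0.497, 319 CPM). Single values were Phlda1 in NCT replicate 5 (0.631, low at 106 CPM), Fasn in PL replicate 5 (0.593, high at 244 CPM), mt-Nd6 in NT replicate 8 (0.577, low at 1.06 CPM), total counts of NT replicate 3 (0.549, high at 14148601), Mcm2 in PL replicate 1 (0.508, low at 9.70 CPM) and Calr in NCT replicate 4 (0.494, high at 1667 CPM).

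C cell transcripts were lower in lesions than beside them. Parathyroid tissue as the whole cause is argued against for the 5 fallen members by their median of -3.38 without the 3 mice high in Pth. These 5 were picked by their calls with all mice, which favours such a result. A higher follicular share alone is argued against by a difference of -2.04 between the C cell median and that of 4 other non-follicular lists. Fewer C cells in the captured lesion tissue and a change within C cells cannot be told apart. The 10 tested members did not move alike, with Scg5 at 9.73 standard errors from their mean, but other secretory cells make Scg5, so this excludes neither.

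Thyroid differentiation genes moved apart in lesions. A higher share of follicular cells would move them together, and 50 percent of the 22 tested members lay over 2 standard errors from their mean. A change of follicular cells in the lesion was not tested and stays open, as do differing cell types in the captured areas for single genes.

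Fasn and Agpat2 were lower in normal tissue of exposed mice. The library high in Lipf is argued against as the whole cause by Fasn at -1.10 without it, and the mouse number series by -1.44 with the series as a covariate. With the adipocyte score Fasn went from -1.25 (SE 0.20) to -0.53 (SE 0.20) and Agpat2 from -1.40 (SE 0.23) to -0.61 (SE 0.23), and the calls ended because the changes shrank. Fat captured with the control thyroid, an effect of exposure and an effect of a nearby lesion cannot be told apart. The score differs between the groups, follicular cells express Fasn too, and every exposed mouse bore a lesion.

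Counts of splits include the actual grouping. For numbers of genes, no other drawn split reached the actual count for PL against NT (1 of 40 splits as large, 445 genes against at most 41 in the others) or PL against NCT (1 of 60, 1433 against at most 2). This argues against chance as far as 40 and 60 splits can show. For NT against NCT chance could not be excluded (3 of 60, 4 against 93). The split with 93 genes put the 4 libraries over 2000 CPM of Pth on 1 side, a structure of the samples. Chance could not be excluded for numbers of lists in PL against NT (6 of 40, 13 against 17), NT against NCT (11 of 60, 12 against 16) or PL against NCT (23 of 60, 9 against 15). The sex tests called 0 genes, a count that any split must match, so the 40 splits of each could show nothing about chance. The other splits called at most 1 and 205 genes. For PL against NT a further 10 splits that parted fewer pairs gave at most 0 genes and 13 lists.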

How the results depend on the processing

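Fits without libraries high in Pth or Lipf, with the adipocyte score and within 1 mouse series were chosen after the data were seen. No named gene that passed changed direction under the alternatives run. Genes that did not pass crossed 0 in 38 values of those picked by the naming rule and in 1 of Ctsl (NT against NCT, -0.10, to 0.21 with the series covariate), none past the threshold. Among the 38 were Slc5a5 in PL against NT (0.16, to -0.46 without the mice high in Pth), NT against NCT (-0.07, to 0.12 without libraries high in Pth) and PL against NCT (0.43, to -0.29 in females). Others were Lgals3 in PL against NCT (0.10, to -0.47 within 1 series) and in NT against NCT, with the adipocyte score, Lpl (-1.01, to 0.02) and Tshr (0.32, to -0.11). The median of the lysosome list went from 0.17 to -0.02 there. For PL against NT, 445 genes became 201 with a 2-fold cutoff, 1285 with DESeq2 (594 higher, 691 lower), 959 with limma-voom, 832 without a filter, 6 in females and 95 without the mice high in Pth. Leaving out 1 mouse gave 137 to 529. Without the block 402 passed, 301 of them among the 445. For NT against NCT, 4 genes became 134 with DESeq2, 7 with limma-voom, 15 without a filter, 1 in females, 7 with the series covariate, 0 without libraries high in Pth, 0 within 1 series and 0 with the adipocyte score. Leaving out 1 library gave 0 to 12. For PL against NCT, 1433 genes became 625 with a 2-fold cutoff, 450 in females and 264 within 1 series, and leaving out 1 library gave 1126 to 1655. Lists called went from 13, 12 and 9 to 0, 0 and 0 with an estimated correlation and to 2, 1 and 5 with fry, and for PL against NT to 7 without the mice high in Pth. The sex difference of PL against NT went from 0 to 2 genes with DESeq2. The fits in females, without libraries or within 1 series hold fewer samples, the 2-fold cutoff is stricter, and the cause was not tested for the other changes. Other scalings, the stricter filter, removal of abundant genes and sex as a covariate kept every count within 1.5 times. They still ended calls of named genes, at most 12 of 72 in PL against NCT (sex), 1 of 41 in PL against NT and 1 of 3 in NT against NCT (Runx1, upper-quartile factors). With all 27 libraries in the fit 5 genes passed for NT against NCT, and the call of Runx1 ended. For PL against NCT 1817 passed there, and 3 of 72 calls of the naming rule ended. On simulated counts for PL against NT, NT against NCT and PL against NCT, 53.8, 47.0 and 59.4 percent of 2-fold changes were recovered. For 1.5-fold changes the shares were 24.2, 20.9 and 16.7 percent, so many changes of these sizes can stay uncalled.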

Other observations

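The lysosome list was chosen after some lysosomal genes had been seen to rise, with 60 genes set down from textbook knowledge, so tests of it as a list show nothing independent of that and are left out. In lesions against normal tissue of the same mice 8 of the 60 rose and 0 fell over all genes, and 52 did not pass. Of all 14461 tested genes 255 were higher and 190 lower. Since the list followed from rises already seen, these shares test nothing. The proteases Ctsl (1.27, SE 0.17, adjusted p = 0.00537) and Ctsb (1.20, SE 0.20, adjusted p = 0.00937), the cholesterol carrier Npc2 (1.53, SE 0.29, adjusted p = 0.0236), Ctsa (0.77, SE 0.16, adjusted p = 0.0228) and the galactosidase Glb1 (0.70, SE 0.13, adjusted p = 0.0135) rose, and Ctsb went from 838 ± 305 to 1912 ± 731 CPM. Cathepsins are known to release hormone from thyroglobulin in follicular cells, and macrophages express these genes too. The number of risen members was 2 without the mice high in Pth, 4 without replicate 3, 3 without replicate 8 and 0 in females. Without the mice high in Pth the calls of Ctsl (1.03, adjusted p = 0.0497) and Ctsb (1.16, adjusted p = 0.0394) stood. Those of Npc2 (1.34, adjusted p = 0.0962), Ctsa (0.58, adjusted p = 0.122) and Glb1 (0.76, adjusted p = 0.0676) ended with fewer mice, while Glb1 was no lower than with all.

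Against non-exposed mice, 22 of the 60 rose and 1 fell in lesions, where 776 of all 14234 tested genes were higher and 657 lower. The number risen was 7 in females, 6 within the shared mouse series and 14 without the libraries high in Pth. Between NT and NCT edgeR called 0 members and DESeq2 0.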
